A study of Mus musculus with 5 samples.

How the data were processed

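The series measured messenger RNA in cells sorted from the lungs of female C57BL/6 mice, aged 7 weeks per the labels, that had received DEP into the trachea. The labels give DEP only as this abbreviation, and the series title speaks of an air pollutant. Per the labels' protocols the dose was 150 µg on 3 consecutive days and the lungs were taken on the next day. SiglecF is a sialic acid-binding receptor found on eosinophils and alveolar macrophages, and neutrophils were divided into those with low and those with high SiglecF. The labels put 2 libraries in the SiglecFlow neutrophil group, 2 in the SiglecFhigh neutrophil group and 1 in the eosinophil group. The antibodies and gates of the sort are not given in the sources used here. RNA was extracted with a micro-column kit, poly-A RNA was selected, and strand-keeping libraries were amplified by 9 cycles of PCR and sequenced on a HiSeq 2500, per the labels' protocols.

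Per the submitters' processing notes the authors used STAR 2.5.4b and RSEM 1.2.31, and the notes name the builds GRCm38 and mm10. The annotation release and the strand setting of the counting are not given in the sources used here. Without the strand setting, reads of a gene and of a gene that overlaps it on the other strand cannot be assigned with certainty. The authors deposited 1 table per library, and per the file headers each holds an expected count per gene, which RSEM estimates by dividing reads that match several genes. Per the file headers the deposited tables also hold TPM, a share of transcripts on a common total. RSEM derives it from the same reads after division by gene length. RSEM's posterior standard deviation of each count, from the deposited tables, was used only to mark genes with uncertain counts. Between 23.9% and 32.6% of a library's counts lay in genes with a fractional count. A deposited table of the whole series was looked at once and not used, because its columns repeat the expected counts of the 5 tables. Its column names carry number prefixes of unstated meaning: both SiglecFlow columns share 1 prefix, each of the SiglecFhigh columns has another, and the name of the eosinophil column ends in 3 numbers. If the prefixes mark a preparation or run, it cannot be told apart from the group, and whether the eosinophil library was pooled is not given in the sources used here.

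Every table holds 51912 gene IDs, of which 51633 matched a symbol and 51719 matched a gene of the GRCm38 annotation that supplied the coordinates. IDs without a symbol held at most 0.037% of a library's counts. Total expected counts were 19227610 and 16946939 in the SiglecFlow libraries, 16982372 and 18731772 in the SiglecFhigh libraries and 22772003 in the library labelled eosinophil. Intervals and floors given for counts cover counting error only, because PCR copies without molecular identifiers are not independent molecules.

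For the main comparison the expected counts were rounded to whole numbers. The 4 neutrophil libraries were fitted with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with the group as the only term, the default filterByExpr filter and TMM scaling. Calls needed a Benjamini-Hochberg adjusted p under 0.05. Standard errors (SE) of log2 fold changes were taken as the fold change divided by the square root of its F value. CPM, counts scaled to a common total, were computed after TMM scaling. Values of groups are the mean ± SD of 2 libraries. The procedure was tested on simulated counts of 14060 genes with the SiglecFlow means, the library sizes and the dispersion trend of these samples. The changed genes, 100 per fold size, lay above a minimum level and went evenly up and down. It called 64% of genes changed 2-fold and 96% of genes changed 4-fold, and 1.8% of its calls were false. The simulation held no shift in composition between the groups and no spread of single genes around the trend. These shares therefore need not hold for the real comparison. Nothing in the labels says that the libraries came from separate mice, so p-values measure only the spread between these samples, which may be technical. The replicates were not copies of each other: chi-square per degree of freedom against sampling noise was 19.1 within the SiglecFlow pair and 45.1 within the SiglecFhigh pair.

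The following were fixed before the data were examined: the tests, 34 gene lists and the rule for named genes. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), which compares a list with all other tested genes, and adjusted over the 33 lists with at least 5 tested members. A list is said to have risen or fallen only where this test passed, and member counts use the adjusted p over all tested genes. Counts adjusted over the list alone are given beside them. An adjusted p with an estimated correlation is given too. That setting rests on the few residual degrees of freedom of 4 libraries, so a list can fail it without correlated members. The rule named, between the neutrophil groups, the 12 largest rises and 12 largest falls among called genes with a mean of at least 20 CPM in the higher group and no overlap between the groups. It also named up to 2 rising and 2 falling called members of each list, or the 2 most abundant where none was called, and 18 genes chosen in advance, and passed over predicted genes, clone names, pseudogenes and antigen receptor segments. Of 672 list members, 670 were found. Azu1 and Ero1a were not.

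With 1 library labelled eosinophil no test was made. CPM in comparisons with that library are scaled over 5 libraries and so differ slightly from those of the neutrophil comparison. A gene was taken as higher when that library had at least 50 CPM and at least 8-fold more than each of the 4 neutrophil libraries, on CPM + 1 with TMM scaling over all 5 libraries, and as lower when all 4 neutrophil libraries had at least 50 CPM and at least 8-fold more than that library. The rule named the 12 with the largest smallest fold in each direction. The median of each list, eosinophil library against SiglecFlow mean, was placed among 10000 random lists matched on expression. The position of SiglecFhigh neutrophils was described by the covariance of both differences from SiglecFlow, beside 100 simulations of unchanged groups against the same SiglecFlow libraries.

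Alternatives were DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1), other scalings (RLE, upper quartile, library totals), no filter and a stricter filter of 5 CPM, a fit on all 5 libraries, the replicate number as a block, a 2-fold minimum, each library left out in turn, an estimated correlation and fry for the lists, and other thresholds for the eosinophil library. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 was used for the rest.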

Results

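Messenger RNA was profiled in cells labelled neutrophils and eosinophils, sorted from mouse lungs after exposure to DEP. The design asked how neutrophils with high SiglecF (SiglecFhigh, n = 2 libraries) differ from those with low SiglecF (SiglecFlow, n = 2), with 1 library labelled eosinophil for comparison. Library totals ran from 16946939 to 22772003 expected counts, and 16656 to 21218 genes had at least 1 count. The 10 most abundant genes took 11.76% and 12.24% of the counts in the SiglecFlow libraries but 6.59% and 6.43% in the SiglecFhigh libraries. Across genes, log2 CPM correlated at r = 0.947 within the SiglecFlow pair, 0.963 within the SiglecFhigh pair and 0.898 to 0.914 between the groups.

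Siglecf, which encodes the sorting marker, checks the labels. It lies on chromosome 7 (43351341 to 43359531, GRCm38; ENSMUSG00000039013) and rose from 40.0 ± 5.12 CPM in SiglecFlow to 418 ± 62.5 CPM in SiglecFhigh neutrophils (SD, n = 2 each). Its log2 fold change was 3.39 (SE 0.173, edgeR adjusted p = 7.76e-06). The eosinophil genes Epx and Prg2, for granule proteins, were at or below 0.223 CPM in every neutrophil library. Ccr3, the eotaxin receptor gene of eosinophils, was at 3.15 to 4.42 CPM with no call (log2 fold change −0.14, SE 0.453, adjusted p = 0.864; above 0 with library totals).

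SiglecFhigh neutrophils had higher levels of Ltc4s, Ptgs1, P2ry14 and Mmp14 and lower levels of Retnlg, Ngp, Ly6g and Cxcr2 than SiglecFlow neutrophils. Of 14060 genes tested, 1709 were higher and 2171 lower in SiglecFhigh than in SiglecFlow neutrophils (27.6% of those tested), and 1036 and 1428 of these changed at least 2-fold. At an unadjusted p under 0.05, 5353 genes passed. The split of calls follows the scaling: 44% of calls were higher with TMM, 32.8% without SiglecFhigh replicate 2, but 85.5% with library totals only (5729 higher, 969 lower), which moved the median log2 fold change of all genes by 0.75. With log2(TPM + 1) the shift was 0.76 and 87.1% were higher (5139 higher, 761 lower). All changes are therefore given relative to the typical gene, as TMM sets it. Without SiglecFlow replicate 1 the higher genes numbered 1098, and without SiglecFhigh replicate 2 they numbered 1137.

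Among called genes with a mean of at least 20 CPM in the higher group and no overlap between the groups, the largest rise was of Krt18 (log2 fold change 3.42, SE 0.499, edgeR adjusted p = 0.00114). Krt18 is a keratin gene of simple epithelia that is also in the lung epithelial list. Siglecf came next (3.39). Pald1, a phosphatase domain gene, rose 9.03-fold and Gpr171, a G protein-coupled receptor gene, rose 7.49-fold. Ltc4s (chromosome 11, 50236461 to 50238616), the synthase of leukotriene C4, rose from 3.24 ± 0.609 to 23.5 ± 3.31 CPM. Ptgs1 (chromosome 2, 36230426 to 36252272), the constitutive cyclooxygenase, rose 6.32-fold, and P2ry14, the receptor gene for UDP-glucose, rose 7.02-fold. The membrane collagenase gene Mmp14 rose 6.33-fold. The signalling genes Scimp and Rgs10 and the transcript AU020206 rose 7.16-fold, 7.14-fold and 6.4-fold. For the 12 largest rises the adjusted p lay between 7.76e-06 and 0.00114.

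By the same rule the largest fall was of Retnlg (chromosome 16, 48872621 to 48874496), a resistin-like gene of neutrophils, from 999 ± 95.8 to 22.8 ± 0.546 CPM (log2 fold change −5.45, SE 0.153, adjusted p = 1.48e-06). Ngp, a granule protein gene, fell from 626 ± 127 to 17.5 ± 9.95 CPM. Ly6g (chromosome 15, 75155240 to 75159126), which encodes the Ly6G surface protein of mouse neutrophils, fell from 36.6 ± 2.62 to 1.75 ± 0.26 CPM. Mmp8, neutrophil collagenase, fell by 4.01 on the log2 scale and Padi4, the enzyme that citrullinates histones during extracellular trap formation, fell by 3.86. The glucose transporter gene Slc2a3 fell by 4.04, the cation channel gene Trpm2 by 4.20 and the cytokine gene Il15 by 3.87. Rdh12 fell by 4.52, Tgm1 fell by 4.26, Nlrp12 fell by 3.93 and Vnn3 fell by 3.82.

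**Figure D1:**
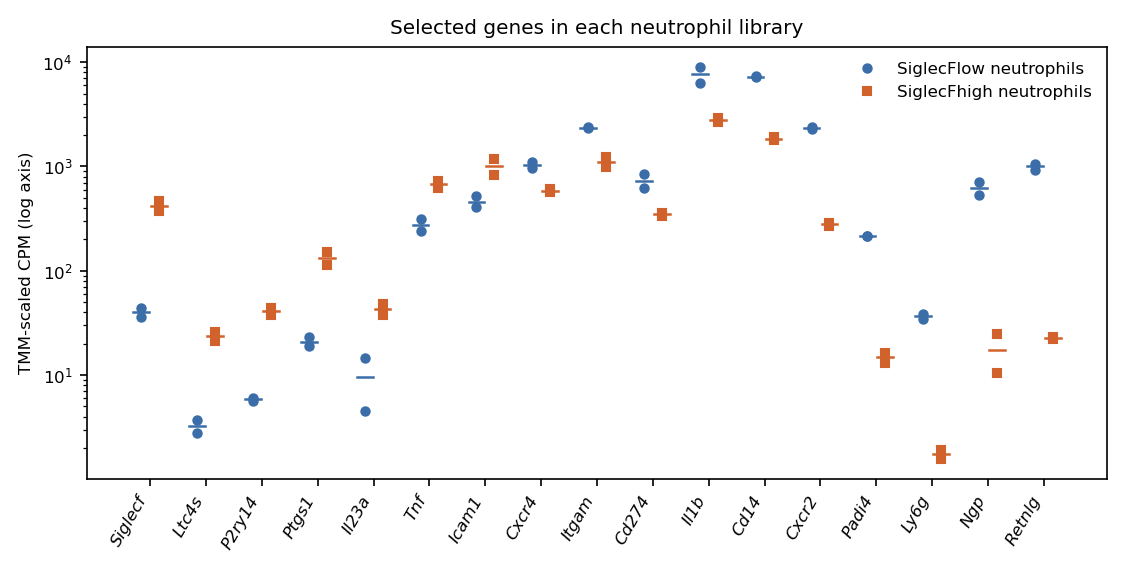
Levels of 17 named genes in each neutrophil library, as TMM-scaled CPM on a log axis; points are libraries (n = 2 per group) and short bars are group means. Siglecf stood at 36.4 and 43.6 CPM in SiglecFlow and at 374 and 463 CPM in SiglecFhigh, and Retnlg fell from 931 and 1067 CPM to 23.2 and 22.4 CPM.

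Genes of mature circulating neutrophils fell as a group: all 20 tested members were lower (20 also when adjusted over the list alone), with a median log2 fold change of −2.99 (camera adjusted p = 2e-14; adjusted p = 0.41 with an estimated correlation). Cxcr2, the receptor for neutrophil-attracting chemokines, fell from 2316 ± 64.5 to 278 ± 12.6 CPM. Early granule protein genes also fell, with 8 of 13 lower, 1 higher and 10 lower adjusted over the list alone (median −2.77, adjusted p = 0.00013; adjusted p = 0.51 with an estimated correlation). Ngp and Mmp8 led these falls. The exception Chil3, a chitinase-like gene, rose 1.65-fold (adjusted p = 0.00799), a call lost without SiglecFlow replicate 1 (edgeR adjusted p = 0.0538) or SiglecFlow replicate 2 (adjusted p = 0.0687). NADPH oxidase and extracellular trap genes fell, with 8 of 15 lower and 1 higher (9 and 2 adjusted over the list alone; adjusted p = 0.013; adjusted p = 0.52 with an estimated correlation). The trap genes Padi4 and Camp fell by 3.86 and 3.64, while the proton channel gene Hvcn1 rose 2.05-fold. With library totals the medians of the first 2 groups stayed at −2.23 and −2.03, and that of the third came to 0.00, with 4 higher and 3 lower. Alveolar macrophage markers moved with the group the other way, with a median of 0.52.

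Type I interferon response genes fell: 19 of 24 were lower and none higher (19 adjusted over the list alone; median −1.58, adjusted p = 2.2e-09; adjusted p = 0.69 with an estimated correlation). Isg20, an antiviral exonuclease gene, fell from 244 ± 4.12 to 22.9 ± 2.91 CPM and Oas3, an RNA-sensing synthetase gene, fell by 3.06 on the log2 scale. Targets of NRF2, the regulator of antioxidant defence, fell in 15 of 20 cases and rose in 1 (15 and 1 adjusted over the list alone; median −1.09, adjusted p = 9.7e-07; adjusted p = 0.47 with an estimated correlation). They included Slc40a1, the iron exporter, which fell by 2.60, and Taldo1, a pentose phosphate pathway enzyme, which fell by 2.37. Of 11 aryl hydrocarbon receptor genes 5 fell and none rose (6 adjusted over the list alone; adjusted p = 0.017, and adjusted p = 0.52 with an estimated correlation). Tiparp fell by 2.30 and Ugt1a6a, which shares exons with its neighbours, by 1.90 (adjusted p = 0.227 with log2(TPM + 1)). With library totals these medians stayed below 0, at −0.82, −0.34 and −0.15, with 14, 9 and 2 members lower and 0, 3 and 1 higher.

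Glycolysis genes fell in 13 of 20 cases and rose in none (14 adjusted over the list alone; median −0.74, adjusted p = 7e-05; adjusted p = 0.47 with an estimated correlation), led by Slc2a3 and by the lactate transporter Slc16a3 (−2.98). Their median was 0.00 with library totals, with 4 higher and 6 lower. Immediate early and heat shock genes, which respond to cell handling, fell in 15 of 21 cases (17 adjusted over the list alone; median −0.82, adjusted p = 0.00027; adjusted p = 0.69 with an estimated correlation), and their median was −0.07 with library totals, with 4 higher and 6 lower. Btg2 fell by 1.72 and Egr1 by 1.58. Antigen presentation and costimulation genes fell in 6 of 19 cases (7 adjusted over the list alone; adjusted p = 0.021; adjusted p = 0.69 with an estimated correlation). The members H2-D1 and B2m encode parts of MHC class I and fell by 1.66 on the log2 scale and 2.3-fold, the latter not called with log2(TPM + 1) (adjusted p = 0.138). The list's median turned from −0.43 to 0.32 with library totals (3 higher and 2 lower), and its call was lost without SiglecFlow replicate 2 (adjusted p = 0.072) or SiglecFhigh replicate 2 (adjusted p = 0.11).

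There were 4 lists that rose. This rests on the camera test over all their members, and 1709 of all 14060 tested genes were called higher. Of 21 cell cycle genes 2 rose, here and adjusted over the list alone (median 0.70, camera adjusted p = 0.016; adjusted p = 0.69 with an estimated correlation; adjusted p = 0.11 without SiglecFlow replicate 2). They were Pcna (1.85-fold), a DNA replication clamp, and Mcm5, whose own call was lost without SiglecFlow replicate 1 (adjusted p = 0.0557). Of 27 nuclear oxidative phosphorylation genes 6 rose and 1 fell (5 and 1 adjusted over the list alone; adjusted p = 0.045; adjusted p = 0.77 with an estimated correlation), among them Uqcrc2 of complex III (log2 fold change 1.00). This call was lost without SiglecFlow replicate 1 (adjusted p = 0.26) or SiglecFhigh replicate 2 (adjusted p = 0.19), and with the replicate number as a block (adjusted p = 0.056). Of 35 cytosolic ribosomal protein genes 10 rose and 2 fell (11 and 2 adjusted over the list alone; adjusted p = 0.045; adjusted p = 0.52 with an estimated correlation), with Rps19 2.07-fold higher and Rps9 2.31-fold lower. Its adjusted p was 0.26 without SiglecFlow replicate 1, 0.13 without SiglecFlow replicate 2, 0.08 without SiglecFhigh replicate 2 and 0.099 with the block. With log2(TPM + 1) Rps9 was not called (adjusted p = 0.073). Alveolar macrophage markers rose in 5 of 18 cases and fell in 1 (the same counts adjusted over the list alone; adjusted p = 0.045; adjusted p = 0.77 with an estimated correlation), including the lipase gene Lpl (2.1-fold) and Atp6v0d2 (1.81-fold). Its adjusted p was 0.11, 0.14 and 0.13 without SiglecFlow replicate 1, SiglecFlow replicate 2 and SiglecFhigh replicate 1. The medians of these 4 lists were also above 0 with RLE, upper-quartile and library total scaling. With library totals 9, 22, 33 and 14 of their members were higher and 0, 0, 1 and 0 lower.

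Several lists held members that moved both ways, and camera called none of them. Cytokines and chemokines rose in 5 and fell in 10 of 31 cases (6 and 10 adjusted over the list alone; adjusted p = 0.084). Tnf rose from 277 ± 50.6 to 671 ± 77.9 CPM and Il23a, a subunit of interleukin-23, rose 4.45-fold, whereas Il1b fell from 7652 ± 1982 to 2793 ± 165 CPM and Cxcl3 fell by 2.02 on the log2 scale. Of 22 leukotriene and prostaglandin genes 4 rose and 6 fell (4 and 8 adjusted over the list alone; adjusted p = 0.56). Ltc4s and the cysteinyl leukotriene receptor gene Cysltr1 (6.54-fold) rose, Alox5ap, the 5-lipoxygenase activating protein gene, fell by 1.41, and Alox5 itself was at 160 ± 2.12 and 155 ± 16.2 CPM (log2 fold change −0.04, adjusted p = 0.864). With library totals Alox5 was called higher (0.71, adjusted p = 0.00254). Ltb4r1, the leukotriene B4 receptor gene, fell by 1.22. With log2(TPM + 1) Il1b, Alox5ap and Ltb4r1 were not called (adjusted p = 0.0768, 0.105 and 0.0849). Of 17 genes for extracellular ATP and purine signalling 6 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.98): P2ry14 rose, and Entpd1, the ectonucleotidase CD39, fell from 4318 ± 204 to 574 ± 145 CPM. The adenosine receptor gene Adora3 fell by 3.37, and P2rx1, an ATP-gated channel gene, rose by 3.65 (SE 1.01, adjusted p = 0.0273) from under 1 CPM, a call lost with DESeq2 (adjusted p = 0.255) and limma-voom (adjusted p = 0.0553). With library totals the medians of the first 2 lists turned from −0.29 and −0.12 to 0.46 and 0.62, with 12 and 8 members higher and 5 and 2 lower; the purine list had 7 higher and 2 lower. The mean of the leukotriene list was 0.11, with camera pointing down and fry up, and the test of the purine list pointed down though its median was 0.06, or −0.02 with RLE.

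Surface genes of aged or tissue neutrophils rose in 3 and fell in 8 of 16 cases (4 and 8 adjusted over the list alone, camera adjusted p = 0.17). Siglecf, the gene of the sorting marker, is among those that rose. Icam1 rose 2.18-fold and the lectin receptor gene Clec5a 2.3-fold. Cd14 fell from 7272 ± 79.5 to 1847 ± 80.3 CPM, Tlr4 by 1.48, Itgam (CD11b) by 1.08, Cd274 (PD-L1) by 1.08 and Cxcr4 by 0.83. With log2(TPM + 1) Cxcr4 stood at 0.01 instead, and with library totals Itgam, Cd274 and Cxcr4 were no longer called (log2 fold changes −0.34, −0.33 and −0.08). The list's median turned from −0.60 to 0.15 with library totals, with 7 higher and 2 lower. Of 22 genes named earlier in tumour-associated SiglecFhigh neutrophils 8 rose, Siglecf among them, and 7 fell (8 and 9 adjusted over the list alone, camera adjusted p = 0.98). Adamdec1, a metalloprotease gene, rose from 0.356 ± 0.074 to 10.4 ± 1.78 CPM and Hif1a, the hypoxia-inducible factor gene, fell by 1.26, while Vegfa was not called (log2 fold change −0.43, SE 0.17, adjusted p = 0.097). Vegfa was called lower without SiglecFhigh replicate 1 (adjusted p = 0.000213), with DESeq2 (0.0183), limma-voom (0.0493), RLE (0.0416), no filter (0.0376) and the block (0.0482). Its log2 fold change was 0.33 with library totals and 0.21 with log2(TPM + 1). The mean of the tumour-associated list was 0.42, with the test pointing up, and its median −0.31. With library totals its median was 0.44, with 14 higher and 1 lower.

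Among the other function lists, hypoxia genes rose in 1 and fell in 4 of 20 cases (5 lower adjusted over the list alone; adjusted p = 0.11; 0.014 without SiglecFhigh replicate 2), and Mxi1 fell by 2.07. The member that rose, Car9, had 0 counts in both SiglecFlow libraries and 37 in SiglecFhigh, at least 7.4-fold higher against a floor of 3 counts over the group. Its call was lost without any of SiglecFlow replicate 1, SiglecFlow replicate 2 or SiglecFhigh replicate 1 (adjusted p = 0.162, 0.15 and 0.151), and with DESeq2, limma-voom, no filter, 5 libraries or the block (0.0549, 0.0864, 0.0537, 0.0591 and 0.102). Lysosome and cathepsin genes rose in 3 and fell in 6 of 27 cases (6 and 8 adjusted over the list alone; adjusted p = 0.47): Gusb rose 2.44-fold, and Lamp2 and Cd68 fell by 1.44 and 1.35. NF-kappaB genes rose in 3 and fell in 7 of 23 cases (4 and 7 adjusted over the list alone; adjusted p = 0.28), with Ikbke up 2.16-fold while Bcl3 fell by 1.37 and Nfkbiz fell by 1.33. Apoptosis regulators rose in 2 and fell in 6 of 23 cases (3 and 7 adjusted over the list alone; adjusted p = 0.42), and Bcl2l11, which encodes the death-promoting protein BIM, fell by 1.60. Lipid handling genes rose in 1 and fell in 5 of 22 cases, also adjusted over the list alone (adjusted p = 0.94), and Hilpda fell by 0.95. Unfolded protein response genes rose in 1 and fell in 4 of 22 cases (3 and 7 adjusted over the list alone; adjusted p = 0.92), and Herpud1 fell by 1.01 and Xbp1 fell by 0.92. With library totals Hilpda, Herpud1 and Xbp1 were not called (−0.20, −0.26 and −0.18), and the medians of the hypoxia, lysosome, NF-kappaB and apoptosis lists, below 0 with TMM, were above 0. The balance of calls then turned: 6 hypoxia genes were higher and 3 lower, 20 and 3 lysosome, 14 and 2 NF-kappaB, 12 and 1 apoptosis, 11 and 0 lipid handling and 13 and 0 unfolded protein genes. The hypoxia list had a mean of 0.03 against a median of −0.30, and the unfolded protein list a mean of −0.03 and a test pointing down against a median of 0.13.

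The share of called markers differed between the lists of other cell types, and 27.6% of all tested genes were called. With library totals the medians of all these lists but the erythroid one (−0.12) were above 0. The members higher were then 4 of the endothelial and fibroblast, 5 of the eosinophil, 5 of the lung epithelial, 3 of the monocyte and macrophage, 2 of the dendritic cell and 1 of the mast cell list, and those lower 0, 1, 1, 1, 0 and 1. With library totals the T and NK cell, B cell and erythroid lists had 0 called. No member was called among 15 T and NK cell, 12 B cell and 16 endothelial and fibroblast genes, also adjusted over the list alone (median log2 fold changes −0.28, −0.17 and −0.02; camera adjusted p = 0.5, 0.49 and 0.5). Without SiglecFhigh replicate 1 the B cell and the endothelial lists fell (camera adjusted p = 0.0035 and 0.0059), and without SiglecFhigh replicate 2 both pointed up (adjusted p = 0.12 and 0.19). Eosinophil markers rose in 2 of 11 cases, Siglecf itself and Adgre1 (2.02-fold), and fell in 1, Il1rl1, which fell by 2.21, also adjusted over the list alone (camera adjusted p = 0.41, fry adjusted p = 0.029). The cells were sorted on SiglecF, and the list was not tested without Siglecf. Monocyte and interstitial macrophage markers rose in 1 and fell in 3 of 17 cases, also adjusted over the list alone (adjusted p = 0.18; 0.047 without SiglecFhigh replicate 1), and Ly6c2 fell by 1.86. Lung epithelial markers rose in 2 of 15 cases, Krt18 and Cdh1 (3.85-fold), and fell in 1, Hopx, also adjusted over the list alone (adjusted p = 0.92; median −0.11, mean 0.11). In the dendritic cell list Itgae rose 4.84-fold, 1 of 12 (1 adjusted over the list alone; adjusted p = 0.23). In the erythroid and platelet list 1 of 9 fell (1 adjusted over the list alone; adjusted p = 0.069, with 0.012 without SiglecFlow replicate 2, 0.047 without SiglecFhigh replicate 1 and 0.019 with the block). This was Hba-a1, a hemoglobin gene, not called without SiglecFlow replicate 1 (adjusted p = 0.101) or with library totals (adjusted p = 0.173). The mast cell and basophil list had 4 tested members, too few for the test (median 0.28, mean −0.16). Of these 1 rose and 1 fell, also adjusted over the list alone, the latter being Hdc, histidine decarboxylase, which fell by 1.94. The former was Kit, not called without SiglecFlow replicate 2 (adjusted p = 0.183) or SiglecFhigh replicate 2 (adjusted p = 0.172). Of 12 mitochondrially encoded genes 2 rose (1 adjusted over the list alone; adjusted p = 0.45; 0.014 without SiglecFhigh replicate 2), and 7 were higher with library totals (median 1.03). For 1 of these 2, mt-Nd4l, RSEM's posterior standard deviation was 56.4% of the count, so its change is uncertain. The other, mt-Nd2, was not called without SiglecFlow replicate 1 (adjusted p = 0.174), SiglecFlow replicate 2 (0.16) or SiglecFhigh replicate 1 (0.152). Mitochondrially encoded genes held 0.57% and 0.65% of the counts in SiglecFlow and 1.13% and 0.65% in SiglecFhigh libraries.

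**Figure D2:**
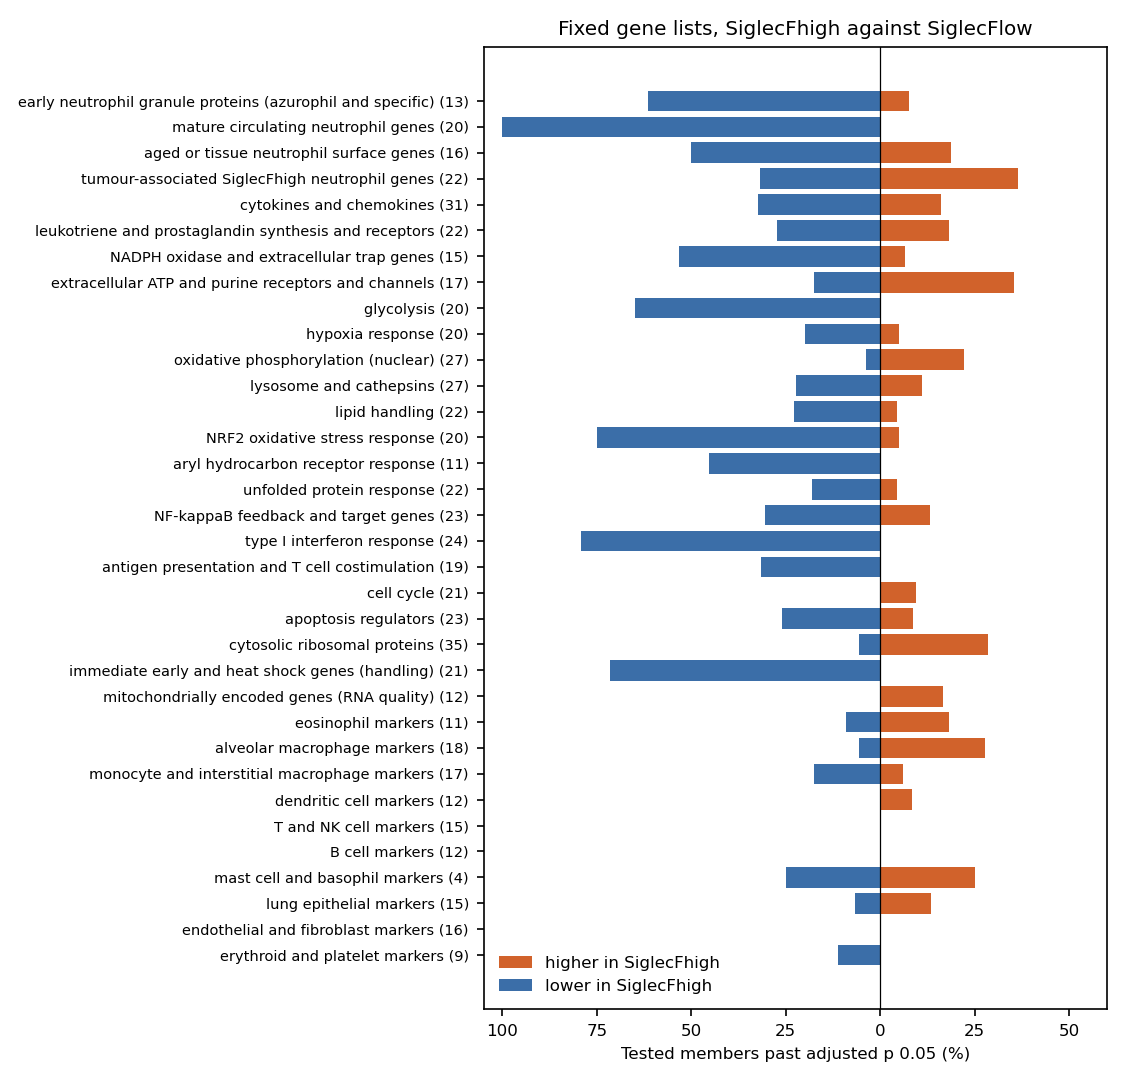
Share of the tested members of each fixed list (number in brackets) that passed an adjusted p of 0.05 in SiglecFhigh against SiglecFlow neutrophils (n = 2 each), drawn to the left when lower and to the right when higher, in percent. All 20 mature neutrophil genes and 19 of 24 interferon response genes lie to the left with TMM scaling; with library totals 18 and 14 did.

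In the library labelled eosinophil, 11 of 19 alveolar macrophage markers and 1 of 16 eosinophil markers were at least 8-fold higher than in every neutrophil library at 50 CPM or more. The granule gene Prg2 (smallest fold 13.8), Ear1 (9.6) and Ccr3 (8.13) also passed 8-fold but lay below 50 CPM; Ear1 was chosen after its values were seen. With that minimum there were 41 genes at least 8-fold higher than in every neutrophil library and 16 at least 8-fold lower, with no replicate and no test. The highest by their smallest fold were Ctsk, cathepsin K (1553 CPM, smallest fold 14.1), the zinc transporter gene Slc39a2 (249 CPM), Mcoln3, a lysosomal channel gene (152 CPM, smallest fold 13.3), Marco, a scavenger receptor gene of alveolar macrophages (568 CPM), and Bhlhe41 (128 CPM, smallest fold 12.8). Gdf15, Adcy3, Ear6, Sh3bgrl2, Plet1, Lpl and Slc9a4 followed, with smallest folds of 12.3 to 10.9. Epx stood at 2.33 CPM (95% exact Poisson interval 1.82 to 2.93), Prg2 at 16.1 CPM (14.7 to 17.6) and Ccr3 at 46.0 CPM (43.7 to 48.5). In the neutrophil libraries these genes stood at most at 0.145, 0.241 and 4.78 CPM. Siglecf stood at 90.2 CPM, above SiglecFlow (38.9 and 46.6 CPM) and below SiglecFhigh neutrophils (405 and 502 CPM). Because these levels leave the identity of the cells open, it is called the library labelled eosinophil throughout.

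Of the genes at least 8-fold lower in the library labelled eosinophil, 3 are in the mature neutrophil list: Mmp9, Il1r2 and Csf3r. Mmp9, gelatinase B, was at 90.1 CPM there and at 1167 to 2321 CPM in the neutrophil libraries. Il1r2, the decoy receptor gene for interleukin-1, Csf3r, the receptor gene for granulocyte colony-stimulating factor, and Hdc were lower by at least 11.8-fold, 10.9-fold and 8.82-fold. The other genes named by the rule were Entpd3, Egln3, Lamb3, G0s2, Il1f9, Asprv1, Mefv and Tarm1, by at least 8.75-fold each. Without SiglecFhigh replicate 1 there were 76 higher genes, and at thresholds of 4-fold and 16-fold there were 189 and 1.

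Of the 34 lists, 10 lay above the 97th percentile of random lists in the library labelled eosinophil against SiglecFlow. Alveolar macrophage markers had the highest median log2 difference, 3.95, with 11 of 19 members past the 8-fold rule (percentile 100), among them Marco, Ctsk, Car4 and Lpl. The eosinophil markers had a median of 1.48 with 1 of 16 members past the rule, Ear6 (percentile 100), and Ear1 and Ear2 are in both lists. Cell cycle genes (2.84), lipid handling genes (2.44), mitochondrially encoded genes (1.99), ribosomal protein genes (1.43), oxidative phosphorylation genes (1.29) and lysosome genes (1.08) were also at percentile 100. Erythroid and platelet markers (1.14) were at 98.3 and the tumour-associated list (−0.29) at 99.5. Mature neutrophil genes (−4.13), early granule genes (−3.48, with Chil3 and Lyz2 past the rule in the other direction), interferon response genes (−2.47) and B cell markers (−0.69) lay below the 3rd percentile. The other 20 lists lay between 11.9 and 96.4, including lung epithelial markers (median 0.03) and endothelial and fibroblast markers (0.11). Mitochondrially encoded genes held 3.34% of the counts of this library (95% Wilson interval 3.33% to 3.35%).

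**Figure D3:**
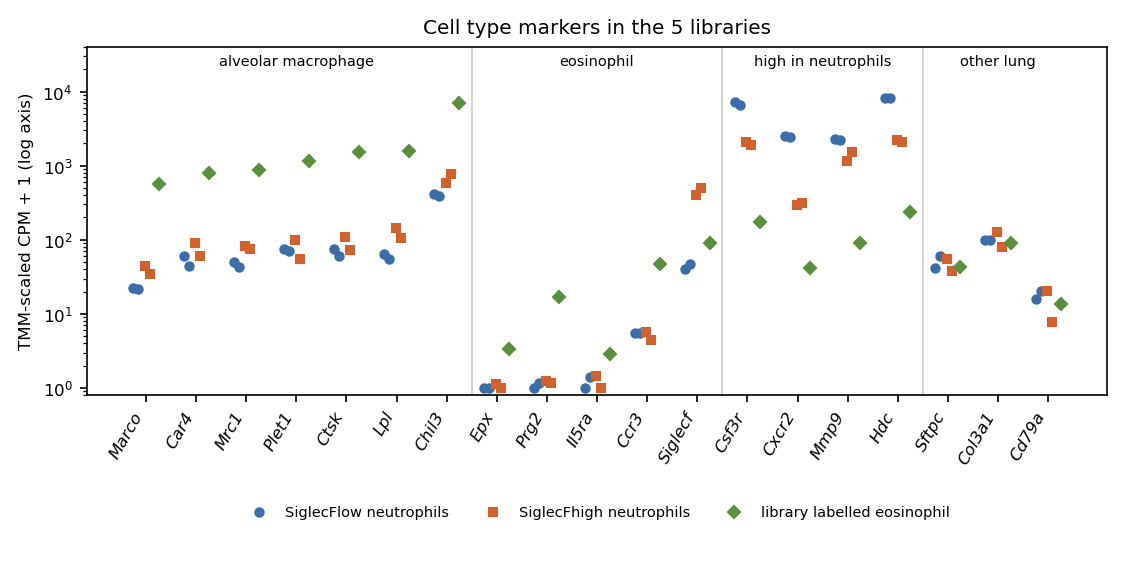
Marker levels in the 5 libraries as TMM-scaled CPM + 1 on a log axis; each point is 1 library, and the genes drawn beyond those the rule names were chosen after their values were seen. In the library labelled eosinophil Marco is at 568 CPM against 20.4 to 42.9 CPM in neutrophils, and Epx at 2.33 CPM.

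SiglecFhigh neutrophils lay nearer than SiglecFlow neutrophils to the library labelled eosinophil. Across 14060 genes, which are not independent replicates, log2 CPM correlated with that library at r = 0.82 and 0.817 for SiglecFlow and at 0.898 and 0.885 for SiglecFhigh. The differences of both from SiglecFlow had a covariance of 0.864, against 0.066 simulated for unchanged groups that share the SiglecFlow libraries, a difference of 0.799. Their correlation was 0.703, against a simulated mean of 0.425, and 0.638 without SiglecFhigh replicate 1. The differences had the same sign for 76.0% of the tested genes, against 63.8% on average in the simulations. Genes called lower in SiglecFhigh and at least 4-fold lower in the library labelled eosinophil than in SiglecFlow numbered 936, and genes higher in both numbered 296. Opposite directions were found for 11 and 1 genes. No simulated value was computed for these 4 counts. Independent lists of the same sizes would share 174.5 lower and 146.3 higher genes, which makes no allowance for the shared SiglecFlow libraries. No such value was computed for the opposite directions. Both differences use the same SiglecFlow libraries. With a different SiglecFlow library as the reference of each, an alternative chosen after seeing the data, the covariance was 0.796 and 0.791 in the 2 assignments, against at most 0.006 in the simulations. The correlation was then 0.606 and 0.604, against at most 0.025 and 0.026. The same sign was found for 70.5% and 71.0% of genes, against at most 51.1% and 51.0%. Whatever both SiglecFlow libraries have in common, such as a run if their shared column prefix marks one, stays in both differences. The simulated groups were unchanged, so these values cannot tell that from a likeness of SiglecFhigh to the library labelled eosinophil.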

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

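The genes at least 4-fold higher in the library labelled eosinophil than in both SiglecFlow libraries were left out after seeing the data. The p-values of the main fit were only adjusted anew, which gave 1458 higher and 2170 lower genes. Without a new fit, this does not show whether the fit depends on those genes. Siglecf rose under every alternative run, by 3.17 to 4.13 on the log2 scale. Counts of higher and lower genes stayed within 1.5 times of 1709 and 2171 with DESeq2 (1445 and 2364), limma-voom, RLE, upper quartile, both filters and all 5 libraries. They left that range with limma on log2(TPM + 1), at 5139 and 761, and with library totals only, at 5729 and 969. By construction these do not correct for composition. A 2-fold minimum gave 1036 and 1428. Leaving out 1 library gave 1098 to 1713 higher and 1621 to 2330 lower genes, with the lone library assumed to vary like the other group; without SiglecFlow replicate 1 there were 1098 and without SiglecFhigh replicate 2 there were 1137 higher genes.

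With the replicate number as a block the calls were 1759 higher and 2197 lower, 1602 and 2084 of them shared with the unblocked fit. The numbers do not show a pairing: deviations of same-numbered libraries correlated at −0.05 over 2 pairs. With the block 3 calls of named genes were lost and 1 gained, and the lists of oxidative phosphorylation (adjusted p = 0.056) and ribosomal proteins (0.099) lost theirs while the erythroid list gained one (0.019).

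Of the named genes, those called and turned in direction did so only with log2(TPM + 1) or library totals, where the typical gene moves up by about 0.75. With log2(TPM + 1) the log2 fold changes were 0.01 for Cxcr4 (0.005 before rounding), 0.211 for Cox8a, 0.035 for Abcg1, 0.40 for Rpl23, which was called higher there (adjusted p = 0.0378), and 0.21 for Cd9. With library totals they were 0.057 for Cox8a, 0.30 for Rpl23, 0.10 for Cd9 and 0.01 for Apoe (0.007 before rounding). Over all tested genes 35 calls turned to the opposite call with log2(TPM + 1) and 13 with library totals. Genes not called in the first place also turned. With log2(TPM + 1) they were Alox5 (0.75), Vegfa (0.206), Ccr3 (0.486), Il7r (0.517), Ighm (0.444), Igkc (0.321) and Col1a1 (0.49), and with library totals Alox5 (0.71), Vegfa (0.327), Ccr3 (0.615), Il7r (0.477), Ighm (0.457), Igkc (0.46) and Col1a1 (0.473). Col3a1 turned with DESeq2 (−0.026) and RLE (−0.042). Leaving out 1 library turned the sign within the ranges of Alox5 (−0.214 to 0.063), Ccr3 (−0.402 to 0.026), Cd2 (−0.471 to 0.739), Ighm (−1.019 to 0.114), Igkc (−1.541 to 0.293), Col3a1 (−0.318 to 0.272) and Col1a1 (−0.749 to 0.009); the cause was not tested. Over all alternatives, 1425 values of named genes kept direction and side of the threshold, 67 lost and 11 gained a call, and 33 turned in direction.

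Of the 13 lists called by camera, 0 held with an estimated correlation. That setting rests on the few residual degrees of freedom of 4 libraries. The mature neutrophil list, with an estimated correlation of −0.036 against the preset 0.01, went to a camera adjusted p of 0.41. The interferon list, with 0.575, went to 0.69. A call lost there is therefore by itself no sign of correlated members. Under fry, which tests whether the genes of a set move one way and does not compare them with other genes, 8 lists passed, the eosinophil list among them, and those of oxidative phosphorylation, interferon response (adjusted p = 0.059), antigen presentation, cell cycle, handling and alveolar macrophages did not; leaving out 1 library left 10 to 16. With library totals, 17 of the 24 lists with a median below 0 came to 0 or above, and the 10 with a median above 0 stayed there. Lists whose test pointed the other way were not called there: leukotriene genes with fry (adjusted p = 0.94), and others when 1 library was left out. Over these fits the adjusted p ran from 0.75 to 0.93 for the tumour-associated list, 0.87 to 0.98 for purine, 0.62 to 0.93 for lipid handling, 0.65 to 0.98 for unfolded protein, 0.014 to 0.87 for mitochondrially encoded genes, 0.096 to 0.93 for T and NK cell, 0.0035 to 0.77 for B cell and 0.0059 to 0.77 for endothelial and fibroblast lists. With RLE 1 list changed sign, and with the upper quartile 0 did.

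For the library labelled eosinophil, a 4-fold rule gave 189 higher and 120 lower genes and a 16-fold rule 1 and 1. Leaving out 1 library gave 42 to 76 higher and 16 to 23 lower genes. Because the rule asks for every neutrophil library, leaving 1 out can only keep or raise these counts. The genes gained in the 76, without SiglecFhigh replicate 1, had missed 8-fold only against that library, and the cause was not tested. Deposited TPM gave 40 and 19, of which 27 and 10 were shared. The correlation of both differences from SiglecFlow was 0.638 to 0.718 when 1 library was left out. It was 0.606 and 0.604 with a different SiglecFlow library as the reference of each difference, chosen after seeing the data. By construction no library is then shared. What both SiglecFlow libraries have in common stays in both differences. With 2 libraries per group, the simulated test called 64% of 2-fold changes at this depth, so smaller changes are often missed. That simulation left out weakly expressed genes from those changed and held no shift in composition.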

Other observations

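All tests in this part were chosen only after the results they bear on were seen. Genes were also grouped by the letters that begin their symbols, giving 219 families of at least 8 tested members. Camera called 9 families higher and 4 lower in SiglecFhigh neutrophils, and 0 with an estimated correlation (adjusted p = 0.88 for each of these 13). Few residual degrees of freedom stand behind that setting, so this loss is by itself no sign of correlated members. Of 49 genes for large subunit proteins of the mitochondrial ribosome (Mrpl) 9 rose and 1 fell (median log2 fold change 1.04, camera adjusted p = 0.00038), and of 29 for the small subunit (Mrps) 6 rose and none fell (0.63, adjusted p = 0.035). Nuclear pore genes (Nup) rose in 9 and fell in 2 of 20 cases (0.96, adjusted p = 0.022), RNA polymerase genes (Polr) rose in 5 and fell in 1 of 28 (0.81, adjusted p = 0.019), and COP9 signalosome genes (Cops) rose in 6 of 9 (1.03, adjusted p = 0.029). Proteasome regulatory subunit genes (Psmd) rose in 5 of 14 (0.55, adjusted p = 0.038). The families Utp, Rad and Dnajc were the other 3 called higher (medians 0.75, 0.88 and 0.69). These medians were also above 0 with RLE, upper-quartile and library total scaling. With library totals the members higher were 37 of Mrpl, 19 of Mrps, 16 of Nup, 20 of Polr, 8 of Cops, 14 of Psmd, 9 of Utp, 9 of Rad and 17 of Dnajc, with 1 lower in Mrpl and in Nup. Not called were Rps (adjusted p = 0.46), Rpl (0.51), Med (0.17), Taf (0.34), Psmb (0.66) and Ube (0.89).

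Among the families called lower, Toll-like receptor genes were lower in 7 of 10 cases: Tlr1, Tlr2, Tlr4, Tlr5, Tlr6, Tlr8 and Tlr13, receptors for microbial products, while Tlr9 was higher (median −1.22, camera adjusted p = 0.037). UDP-glucuronosyltransferase genes (Ugt) fell in 6 of 8 cases (−1.88, adjusted p = 0.031), but those of the Ugt1a cluster share exons, so they are not separate observations. Genes beginning with Il, for interleukins and their receptors, fell in 18 and rose in 3 of 51 cases (−0.54, adjusted p = 0.014). The Rap family fell in 5 of 8 cases (−0.68, adjusted p = 0.022). With library totals the medians of the first 2 families stayed at −0.46 and −1.13, and those of the Il and Rap families turned to 0.21 and 0.07. The members lower were then 6 of Tlr, 4 of Ugt, 12 of Il and 3 of Rap, and those higher 1, 0, 7 and 2. With an estimated correlation the adjusted p of each was 0.88.

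The high alveolar macrophage markers in the library labelled eosinophil are a pattern to follow up. Free RNA of the whole lung is argued against: the medians of the epithelial and of the endothelial and fibroblast lists were 0.03 and 0.11, against 3.95 for the alveolar macrophage list, a gap larger than the spread of their members (SD 0.93 and 0.2). RNA of alveolar macrophages, which also carry SiglecF, is a candidate explanation that stays open: of the 8 list members not past the 8-fold rule 7 lay above all 4 neutrophil libraries and Cd9 did not, which decides nothing, with Lyz2 at 13817 CPM, Chil3 at 7011 CPM, Ctsk at 1553 CPM and Marco at 568 CPM. The gates that would remove them are not given in the sources used here, 2 of the 19 markers are also in the eosinophil list, and Chil3 and Lpl are in other lists. A sample of another cell type under this label cannot be told apart from a mixed sample or from expression by lung eosinophils themselves, because 10 of 14 eosinophil genes outside the macrophage list lay above all 4 neutrophil libraries, several at low levels, and there is 1 such library, whose column name ends in 3 numbers of unstated meaning.

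The fall of mature neutrophil genes in SiglecFhigh neutrophils was set against explanations from sample makeup and scaling. A lower share of neutrophils with all other cell types raised alike is not decided. The log2 changes of the 20 genes had an SD of 1.21 (from −0.78 to −5.45) against a mean SE of 0.16, so they did not share a common fall. Other cells that carry some of these genes would also make the falls unequal. The medians of the alveolar macrophage and the erythroid and platelet lists lay 1.40 apart, against an SD of their members of at most 0.57. These lists were picked as the highest and lowest of 10, and 1 of 9 erythroid and platelet genes was called. Of 10 marker lists of other cell types 3 had a median above 0 with TMM and 9 with library totals, so that count was not used, and a rise of 1 other cell type stays open. Scaling is argued against as the whole cause, since 18 of the 20 genes stayed lower with library totals. A preparation or run that follows the column prefixes of the series table cannot be told apart from the group, and a difference between the sorted states that the design names stays open.

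The dependence of the split of calls on scaling was weighed last. With library totals the typical gene was higher in SiglecFhigh neutrophils by 0.88. Leaving the 50 most abundant genes out of the totals left 0.72, and leaving out 500 left 0.49, so a few abundant genes such as Thbs1 account for part of the shift at most. Dividing each library by its own total already removes a difference in library size. The factor of 1.013 between the mean totals is therefore no evidence on it. A broader fall of abundant neutrophil transcripts, which raises the share of all others, is a hypothesis that stays open, and RNA content per cell was not analysed here.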
